A study of Sus scrofa with 22 samples.

How the data were processed

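RNA of single cells was measured by a modified Smart-seq2 protocol with cell barcodes, in 20 libraries of cells from pig embryos of embryonic day 0 to 14 and in 2 libraries of pgEpiSC cells. RNA of the External RNA Controls Consortium (ERCC) was present as a spike-in. The submitters' processing notes list STAR 2.7.1a, featureCounts 1.6.4, UMI-tools and the genome build Sscrofa11.1, without the role or the order of each.

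The deposited count table holds raw counts for 29306 features, 29214 pig genes and 92 spike-ins, in 1647 cells. A second deposited table gives for each of the authors' 39 groups the mean over cells of log2(CPM/10 + 1), where CPM are counts scaled to a total of 1e+06 over pig genes; for the 37 embryonic groups its unit was recorded as other, since several columns belong to the same samples. A further table gives the standard deviation over cells on the same scale, a unit again recorded as other. Both hold 25749 genes. No further file of the series was analysed here. Genes were named by the reference annotation for 14800 identifiers and by the authors' table alone for 1161 more, and no gene carried the name XIST.

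The cell names gave the library but not the stage. The authors' grouping was therefore recovered from the deposited means, by least squares of each group's mean on the log2 values of all cells. Each of the 1647 cells received weight in exactly 1 group. With cells grouped this way, at least 93.22% of a group's means and 99.97% of its standard deviations were within 0.001 of the deposited values. The plan made a test of stages conditional on cell names that give the stage, so its use with the recovered grouping is a departure from it.

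Total counts per library ran from 7415760 to 39405309. A cell had from 5274 to 1796832 counts, with a median of 274531, and at least 2080 detected genes. Spike-ins took 1.80% of all counts and were left out of every comparison. Counting intervals are exact Poisson or Clopper-Pearson intervals at 95% and cover counting error alone, as does the floor of 3 counts.

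Counts were added over the cells of a group in a library, and a sum entered a test with at least 5 cells (2 for Zygote, 2C and 4C, 1 for Oocyte). Tests used edgeR 4.0.16 in R 4.3.3, with filterByExpr, TMM normalization, common and trended dispersion and the quasi-likelihood F-test, and Benjamini-Hochberg adjustment with a threshold of 0.05. Each stage was set against the nearest earlier group of its lineage in a single fit, without the library as a block. TE_E9, with 2 cells, entered no step, so TE_E10 was set against TE_E8. This gave 15 comparisons with at least 2 libraries in both groups, of which TE_E10 against TE_E8 was tested only after its pooled values had been seen; 18 further steps had too few libraries and are given as pooled values without a test. The 4 lineage comparisons had the library as a block and needed at least 3 blocks. The pgEpiSC sums were set against Epiblast_E10, the day that the labels name, with the other epiblast days in the same fit. With 1 library per group, pgEpiSC_high and pgEpiSC_low were compared without a test, by log2 ratios of CPM with a pseudocount of 1.

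The groups, tests, thresholds, alternatives, 26 gene lists with 327 genes and the rule for naming genes were fixed before the data were examined. The comparison of mesoderm with ectoderm and the set of germline genes were chosen afterwards. Named by the rule were, per direction, the 12 genes with the largest log2 change past the threshold, with at least 50 CPM in the higher group and the same direction in every sum, together with members of the fixed lists and with POU5F1, SOX2, NANOG, TBXT and XIST. Without a test the rule took the 12 largest log2 ratios with at least 50 CPM and 100 summed counts. Ribosomal and mitochondrial genes and genes known only by an identifier were counted but not named for size.

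Lists were tested with camera in limma 3.58.1, with the preset correlation of 0.01, and again with an estimated correlation and with fry. For pgEpiSC_high against pgEpiSC_low a list was placed among 10000 random lists matched on mean expression. Similarity was Spearman's correlation across the 2000 genes that varied most between the embryonic groups, on log2(CPM + 1), with the range over 100 random draws of 50% of the cells; genes are not independent replicates. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and matplotlib 3.10.9 for the plots.

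The alternatives were DESeq2 1.42.0 as the test, its size factors within edgeR, no filter on low counts, each library left out in turn, mitochondrial genes left out, at least 10 cells per sum, no block, and the neighbouring epiblast days. Values without a test were recomputed with another pseudocount, minimum or scaling, from the mean CPM over cells and from the deposited means. Added after the data were seen were a minimum of 6000 detected genes per cell, which removed 114 cells, a quasi-likelihood fit without trended dispersion, pgEpiSC and Epiblast_E10 sums thinned to equal totals, fits of the 2C and 4C sums alone with and without the library as a block, and a comparison of pgEpiSC with Ectoderm_E11.

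The procedure was tested on simulated data with 100 genes changed by each of 2 folds. Of those changed 2-fold, 2% were recovered for 8C against 4C, 74% for hypoblast against epiblast and 50% for pgEpiSC against epiblast, and of those changed 4-fold 55%, 100% and 100%. Of the unchanged genes 3, 6 and 8 were called. Only genes with a mean of at least 50 CPM were changed. The simulated spread lay on the fitted trend of dispersion, without differences between libraries, so these rates need not hold for the real sums.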

Results

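The series measured polyadenylated RNA in single cells of pig embryos from embryonic day 0 to day 14 (E0 to E14) and of pgEpiSC, stem cell lines derived from pig epiblast of E10 before gastrulation. There were 22 libraries, 20 of embryonic cells (P1 to P20) and 2 of pgEpiSC, labelled low and high. What low and high stand for, and whether these are separate lines, is not given in the sources used here. They held 1647 cells, of which 1458 were embryonic, 93 pgEpiSC_low and 96 pgEpiSC_high. Library totals ran from 7415760 counts in P3 to 39405309 in P15, with 13468167 in pgEpiSC_low and 20019016 in pgEpiSC_high. A cell had a median of 274531 counts and 9120 detected genes. The authors placed the embryonic cells in 37 groups of a stage or a lineage and day, from 2 cells in TE_E9 to 129 cells in Hypoblast_E8, where TE stands for trophectoderm and ICM for inner cell mass. Names such as Mesdoderm and Defi_Endoderm are given as the authors' columns spell them.

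The unit of every test was a sum, the added counts of the cells of a group in a library. Log2 changes are given with an approximate standard error, worked back from the test as the absolute change divided by the square root of its F statistic. Levels are CPM (counts scaled to a total of 1e+06) after TMM scaling, averaged over the sums of a group. Values of a single sum or of pooled cells are CPM of its total, without TMM scaling. Each comparison of stages was tested on 23045 genes in a fit of 65 sums. The p-values measure the spread between library sums alone, which may be technical, since the labels do not say that libraries come from separate embryos. In most stage steps the earlier and the later sums come from wholly different libraries. There the test cannot tell a difference between stages from a difference between libraries. In the few steps with a shared library, the fit of all stages does not pair its sums. A gene named for the size of its change moved the same way in every sum compared. Sets of genes were fixed before the data were examined, and a set's adjusted p is that of camera with its preset correlation unless the text says otherwise.

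From the 2-cell to the 4-cell group, which asks what the cleaving embryo begins to transcribe, most genes that passed were higher: 1041 genes passed, 1022 higher and 19 lower in 4C (2 sums against 2, 23 cells against 10). IGF2BP1, a protein that binds messenger RNA (ENSSSCG00000023128), rose by 5.66 ± 0.89 on the log2 scale, from 2.37 to 128 CPM. GATA6, a transcription factor of the hypoblast (ENSSSCG00000003702), rose by 4.08 ± 0.72, the histone demethylase KDM5B by 4.33 ± 0.71, and TFAM, which maintains mitochondrial DNA, by 4.02 ± 0.71. Of 18 measured genes of oxidative phosphorylation, 8 rose, among them COX4I1 (2.16 ± 0.38) and COX7A2 (2.01 ± 0.36), and none fell (11 when adjusted over the list alone, adjusted p = 6.56e-09). Of 7 genome activation genes, 3 rose, KDM5B, DPPA2 (4.08 ± 0.95) and the chaperone HSPA8 (1.86 ± 0.37), and none fell (6 adjusted over the list alone, adjusted p = 0.000567). Both list results had adjusted p = 0.511 with an estimated correlation. NANOG, a pluripotency factor (ENSSSCG00000040403), rose by 5.40 ± 1.36, and stood above the 2C mean in 1 of the 2 4C sums, that of P1. The values for SOX2 (1.65 ± 0.89) and POU5F1 (0.49) did not pass. RNFT1 and SNX2, a sorting nexin, fell by 1.90 ± 0.58 and 1.61 ± 0.43.

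The 4C cells of the libraries P1 and P13 differed. Across the 2000 genes that varied most between early groups, which are not replicates, the P1 sum of 17 cells had a Spearman correlation of 0.753 with the pooled Morula_E4 profile and 0.17 with the 2C profile. The P13 sum of 6 cells had 0.081 and 0.866. GATA6 stood at 275 CPM of the library sum in 4C of P1 and at 12.7 in 4C of P13, beside 12.9 and 7.56 in the 2C sums. IGF2BP1 stood at 327 and 5.61, KDM5B at 313 and 12.2, NANOG at 33.9 and 0.51, and KLF4 at 646 and 33.6 in the P1 and P13 sums. All 17 cells of 4C in P1 were closest to the pooled 4C profile, most of which they make up, while 3 of the 6 in P13 were closest to Zygote and 3 to 2C. Without P1, edgeR called 0 genes between 4C and 2C (452 at an unadjusted p under 0.05), and NANOG had a value of -0.75 and DPPA2 of -0.84. Without P13 it called 1506, of which 325 were lower. Both groups come from these same libraries, which the fit of all stages does not use as a block. In fits of the 4 sums alone, edgeR called 21 genes with the library as a block, 19 higher and 2 lower, and 0 without it (774 at an unadjusted p under 0.05), and no other tool was run on these sums.

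**Figure D1:**
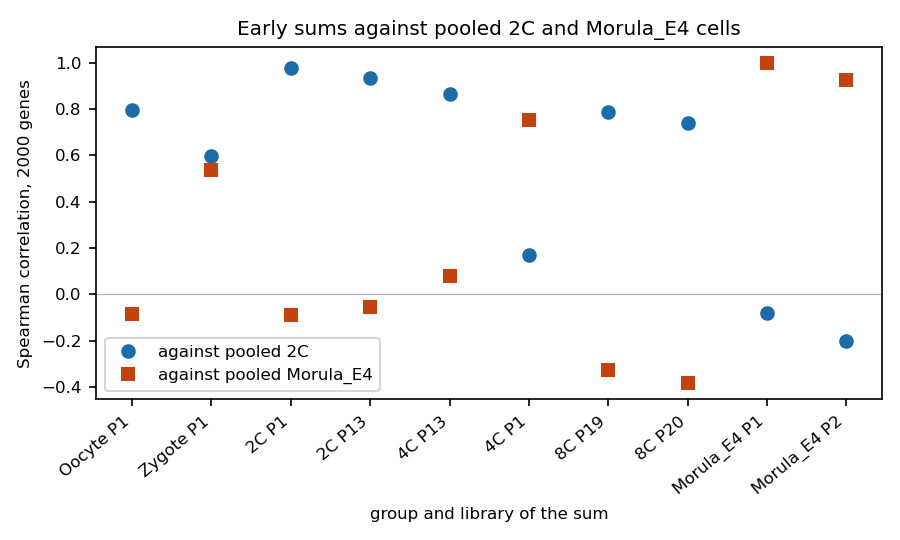
Spearman correlation across genes of each early sum, a group in a library, with the pooled 2C cells (circles) and the pooled Morula_E4 cells (squares). The 4C sum of P1 lies closer to Morula_E4 (0.753), and the 4C sum of P13 lies closer to 2C (0.866).

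From the 4-cell to the 8-cell group genes went both ways: 2591 genes passed, 941 higher and 1650 lower in 8C (2 sums against 2, 80 cells against 23). IGF2BP1 fell by 7.89 ± 0.99, GATA6 by 5.92 ± 0.78 and KDM5B by 4.82 ± 0.71. Of the 1022 genes called higher in 4C than in 2C, 715 were called lower in 8C than in 4C and 3 higher. Both comparisons use the same 4C sums, so high values in these, such as those of P1, favour this overlap. Among naive pluripotency genes 5 of 13 fell, including ESRRB (-6.03 ± 1.37), KLF4 (-3.39 ± 0.89) and NR5A2 (-6.24 ± 1.62), and TFCP2L1 rose. Oxidative phosphorylation genes went both ways, with 2 higher, 8 lower and 8 not past the test (3 and 9 adjusted over the list alone, adjusted p = 0.0534). Higher in 8C were the lysosomal galactosidase GLB1 (4.53 ± 0.63), HORMAD1, a protein of meiotic chromosome axes (3.67 ± 1.23), the replication clamp PCNA (1.46 ± 0.39) and CCNB1, a mitotic cyclin (1.29 ± 0.36). SOX2 fell by 2.71 ± 0.92 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.0447). None of the 26 lists passed camera or fry. All 80 8C cells lay closest to the 2C profile, and the 8C sums of P19 and P20 had correlations of 0.785 and 0.738 with 2C and of -0.326 and -0.383 with Morula_E4. Without P1 the count was 795, with 462 higher and 333 lower and KLF4 at 0.24, and without P20 it was 859. More were higher than lower also without P19 (1187 and 1060) and without trended dispersion (3735 and 3129).

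From the 8-cell group to Morula_E4 came the widest change of all stage steps tested, 6906 genes, 3778 higher and 3128 lower (2 sums against 2, 30 cells against 80). Mitochondrial genes rose together: 15 of 18 genes of oxidative phosphorylation passed and none fell (15 adjusted over the list alone, adjusted p = 2.25e-14, and adjusted p = 0.321 with an estimated correlation), such as UQCRC2 (5.70 ± 0.60) and COX4I1 (4.16 ± 0.41). GATA6 rose by 7.39 ± 0.83, TEAD4, a transcription factor of the trophectoderm, by 5.49 ± 0.72, TBX3 by 4.56 ± 0.62 and ESRRB by 7.87 ± 1.48. The imprint guardian ZFP57 rose by 10.46 ± 1.34 and the CDC42 effector CDC42EP1 by 11.66 ± 1.10. Of 15 oocyte genes 4 fell and none rose (4 adjusted over the list alone, adjusted p = 0.0208), including the oocyte-secreted OOSP2 (-9.04 ± 2.26), BTG4, which directs decay of maternal messages (-5.90 ± 1.79), and MOS, the kinase that holds the egg in meiosis (-4.91 ± 1.74). DNMT1, the maintenance DNA methyltransferase, fell by 3.21 ± 0.62, from 4025 to 434 CPM. Of 7 genome activation genes 5 rose (5 adjusted over the list alone, adjusted p = 0.0139), of 17 glycolysis genes 7 rose and LDHA fell (7 and 1 adjusted over the list alone, adjusted p = 0.044), and of 16 formative genes 7 fell, OTX2 among them (-2.65 ± 0.66), and ZIC2 rose (7 and 1 adjusted over the list alone, adjusted p = 0.044). Under an estimated correlation these lists had adjusted p = 0.834 (oocyte, glycolysis, formative) and adjusted p = 0.79 (genome activation). In all, 1565 genes were lower in 8C than in 4C and higher again in Morula_E4, and 701 of these were also higher in 4C than in 2C. These comparisons share the 8C or the 4C sums, which favours such overlaps. With DESeq2 size factors the median of all genes moved from 0.0 to -0.47 and the share of called genes that were higher from 54.7% to 41.6%. Without P2 the count was 4194 and without P20 it was 4150. More were lower than higher also without P19 (3547 and 2248), with mitochondrial genes left out (3892 and 3244), with no filter on low counts (4303 and 2880), with at least 6000 genes per cell (4177 and 3397), without trended dispersion (5005 and 4748) and by DESeq2 (4333 and 3449).

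From ICM_E6 to Epiblast_E7, the founding of the epiblast, 423 genes passed, 259 higher and 164 lower (2 sums against 2, 35 cells against 32). The de novo DNA methyltransferases DNMT3B and DNMT3A rose by 3.14 ± 0.80 and 2.51 ± 0.66, DND1, a protein of germ cells that binds RNA, by 2.71 ± 0.48, and the intermediate filament VIM by 5.0 ± 1.31. Of 16 hypoblast genes 2 rose and 2 fell, GATA6 by 2.82 ± 0.68 and the growth factor receptor PDGFRA by 3.34 ± 0.68 (3 and 3 adjusted over the list alone, adjusted p = 0.607). Of 10 LIF pathway genes STAT3 (-3.06 ± 0.58) and IL6ST, its shared receptor chain (-2.41 ± 0.50), fell and none rose (3 adjusted over the list alone, adjusted p = 0.0516). KLF4 and TBX3, both of the naive state, fell by 3.56 ± 0.91 and 2.05 ± 0.57. The largest changes among named genes were increases of PLA2G7, a phospholipase of plasma (8.71 ± 1.77), and of GFRA2, a receptor for neurturin (7.03 ± 1.37), and decreases of the sphingomyelinase relative SMPDL3A (-6.75 ± 0.73) and the arginase ARG1 (-6.06 ± 1.38). NANOG had a value of 2.67 ± 1.05, with 275 CPM in Epiblast_E7 and 43.2 in ICM_E6, which did not pass edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.212). Without P14, P15, P8 or P9 the count was 137, 117, 84 or 200, and without P14 more were lower (82) than higher (55).

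From Epiblast_E7 to Epiblast_E8, 137 genes passed, 100 higher and 37 lower (2 sums against 2, 15 cells against 35). NODAL, the signal that patterns the epiblast, rose by 5.57 ± 1.32, from 2.0 to 102 CPM, with ETV5, a target of FGF signalling (5.01 ± 1.24), the BMP target ID3 (3.31 ± 0.78) and the homeobox gene HHEX (4.82 ± 0.88). HHIP, which binds hedgehog, rose by 7.96 ± 1.73, and IL6ST fell by 2.26 ± 0.52. PBK, a mitotic kinase, fell by 2.98 ± 0.43. Of 16 formative genes 2 rose (3 adjusted over the list alone, adjusted p = 0.0257), of 15 BMP genes 1 (3 adjusted over the list alone, adjusted p = 0.00697), of 10 p53 and stress genes 1, GADD45A (4 adjusted over the list alone, adjusted p = 0.00697), and of 16 FGF genes 1, ETV5 (1 adjusted over the list alone, adjusted p = 0.0232). The WNT list tended up although only WNT8A passed, downward (3 up and 1 down adjusted over the list alone, adjusted p = 0.0216). No gene of oxidative phosphorylation or naive pluripotency passed, and both lists leaned down (0 of 18 adjusted over the list alone, adjusted p = 3.39e-06; 2 of 13, adjusted p = 0.0443). With an estimated correlation the formative list had adjusted p = 0.419 and the other 6 had adjusted p = 0.391. Without P4, P5, P8 or P9 the count was 63, 5, 3 or 26, and without P8 it held 1 higher and 2 lower.

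Between Epiblast_E10 and Ectoderm_E11, the step into gastrulation, 38 genes passed, 34 higher and 4 lower (2 sums against 2, 102 cells against 97). Among the largest increases were WNT5A (7.14 ± 1.21), the WNT amplifier RSPO3 (6.37 ± 0.89), BMP4 (3.78 ± 0.83), HAND1, a factor of extraembryonic mesoderm and heart (6.31 ± 1.21), the VEGF receptor KDR (8.83 ± 1.85; ENSSSCG00000008844) and CYP26A1, which degrades retinoic acid (6.96 ± 1.19). GATA6 rose by 4.91 ± 0.74, GATA4 by 4.63 ± 0.86 and FOXA2 by 6.37 ± 1.44, so that 5 of 16 hypoblast genes rose (6 adjusted over the list alone, adjusted p = 7.69e-12, and adjusted p = 0.00427 with an estimated correlation). Of 12 genes of primitive streak and mesoderm 1 rose (6 adjusted over the list alone, adjusted p = 4.66e-08), and of 7 definitive endoderm genes 1 rose (3 adjusted over the list alone, adjusted p = 4.54e-05). Under an estimated correlation these had adjusted p = 0.00171 and adjusted p = 0.00427. LDHA, which makes lactate, rose by 2.22 ± 0.50 as 1 of 17 glycolysis genes (10 adjusted over the list alone, adjusted p = 6.89e-07, and adjusted p = 0.091 with an estimated correlation). POU5F1 had a value of 0.55 and SOX2 of -2.14 ± 0.90, and neither passed. The urea cycle gene ASS1 fell by 2.97 ± 0.66. Without P15, P16, P6 or P7 the count was 2, 10, 24 or 17.

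From Ectoderm_E13 to Ectoderm_E14 core pluripotency genes fell: 62 genes passed, 14 higher and 48 lower (3 sums against 2, 123 cells against 85). POU5F1 (ENSSSCG00000001393) fell by 4.28 ± 0.55, from 348 to 18.2 CPM (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 9.39e-06). NANOG fell by 6.48 ± 1.25, GDF3 by 6.09 ± 1.01 and the NODAL coreceptor TDGF1 changed by -9.36 ± 1.36, and 5 of 13 core pluripotency genes fell in all (8 adjusted over the list alone, adjusted p = 8.92e-12, and adjusted p = 0.00107 with an estimated correlation). SOX2 (ENSSSCG00000037485), which neural cells keep, had a value of -0.08 ± 0.78. NODAL (-7.52 ± 1.20) and the streak genes EOMES (-7.52 ± 1.40) and GSC (-8.88 ± 1.38) fell with them. HOXA5 and HOXC6, which mark position along the body, rose by 10.42 ± 1.78 and 7.43 ± 1.69, and the troponin TNNT2 by 10.80 ± 2.36. The fibroblast collagen COL3A1 rose by 6.23 ± 1.45, as 1 of 10 genes of the fibroblast list (7 adjusted over the list alone, adjusted p = 5.69e-07, and adjusted p = 0.0513 with an estimated correlation). No amnion gene passed over all genes, and 6 of 8 rose when adjusted over the list alone (adjusted p = 1.54e-05, and adjusted p = 0.0058 with an estimated correlation). Without P11, P12, P18 or P19 the count was 16, 18, 11 or 20, and without P13 it was 41. More were higher than lower by DESeq2 (154 and 101), with no filter on low counts (169 and 154) and without trended dispersion (1220 and 669).

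Between Mesdoderm_E13 and Mesdoderm_E14, edgeR called 0 of 23045 genes (2 sums against 2, 22 cells against 20), with 1815 at an unadjusted p under 0.05, and DESeq2 called 179. Collagen genes had the values 4.08 ± 1.45 for COL1A2, 2.90 ± 1.25 for COL3A1 and 2.47 ± 0.93 for COL1A1. The fibroblast list of 10 genes leaned up (3 adjusted over the list alone, adjusted p = 9.55e-06), as did the 8 amnion genes (0 adjusted over the list alone, adjusted p = 0.00657), with adjusted p = 0.195 and adjusted p = 0.192 with an estimated correlation. Without P13, P18 or P19 the count was 7, 1 or 1, and without P12 it was 0 (1174 at an unadjusted p under 0.05).

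Along the trophectoderm, few genes passed from Morula_E4 to preTE_E5: 12 genes, 10 higher and 2 lower (3 sums against 2, 60 cells against 30). By DESeq2 146 passed, with no filter on low counts 147 and without trended dispersion 151, so the count does not measure the size of the step. The tropomyosin TPM1 rose by 3.01 ± 0.63 and vinculin, VCL, which ties actin to adhesions, by 2.66 ± 0.53. DAB2, an endocytic adaptor, rose by 2.62 ± 0.52, as 1 of 13 trophoblast genes (2 adjusted over the list alone, adjusted p = 0.00417), and TET1, which oxidizes methylated cytosine, by 2.51 ± 0.52. SMPD1, a sphingomyelinase, fell by 3.90 ± 0.79. No oocyte gene passed and the list leaned down (4 of 15 adjusted over the list alone, adjusted p = 0.000628), while oxidative phosphorylation (0 of 18, adjusted p = 0.000483) and glycolysis (2 of 17 adjusted over the list alone, adjusted p = 0.0112) leaned up. All 4 lists had adjusted p = 0.916 with an estimated correlation. Without P14 the count was 6, and without P1 or P2 edgeR called 0 (913 and 1067 at an unadjusted p under 0.05). With DESeq2 size factors 50% of 2 called genes were higher, against 83.3%.

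From preTE_E5 to TE_E6 trophoblast genes rose, with 1121 genes past the test, 713 higher and 408 lower (2 sums against 3, 75 cells against 60). Of 13 trophoblast genes 7 rose (9 up and 1 down adjusted over the list alone, adjusted p = 6.44e-06, and adjusted p = 0.0628 with an estimated correlation), among them the keratins KRT8 (3.04 ± 0.86, from 461 to 3781 CPM) and KRT18 (2.47 ± 0.60) and the transcription factors GATA2 (4.26 ± 0.84), GATA3 (3.89 ± 0.77) and TFAP2A (3.08 ± 0.66). The actin-capping protein CAPG rose by 4.99 ± 0.57 and RAB25, a GTPase of epithelial recycling, by 5.08 ± 0.92. SOX2 fell by 3.82 ± 0.97, OTX2 by 4.93 ± 0.72, NR5A2 by 6.43 ± 1.68 and STAT3 by 4.26 ± 0.60. Of 10 LIF pathway genes 2 fell (2 adjusted over the list alone, adjusted p = 0.0114, and adjusted p = 0.0704 with an estimated correlation), of 7 definitive endoderm genes 3 (4 adjusted over the list alone, adjusted p = 0.00252, and adjusted p = 0.0628 with an estimated correlation), and of 16 hypoblast genes 2 (4 adjusted over the list alone, adjusted p = 0.0114, and adjusted p = 0.371 with an estimated correlation). Energy genes rose, 5 of 18 of oxidative phosphorylation (13 adjusted over the list alone, adjusted p = 4.38e-10) and 4 of 17 of glycolysis, where SLC2A3 fell (8 up and 1 down adjusted over the list alone, adjusted p = 9.87e-05). With an estimated correlation these had adjusted p = 0.182 and adjusted p = 0.224. With DESeq2 size factors the median of all genes moved from -0.06 to -0.29 and the share of called genes that were higher from 63.6% to 46.4%. More were lower than higher also by DESeq2 (1501 and 961) and with no filter on low counts (945 and 812). Without P13, P14 or P15 the count was 738, 204 or 489.

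From TE_E6 to TE_E7, 174 genes passed, 86 higher and 88 lower (2 sums against 2, 14 cells against 75). Among the genes that rose most were the apolipoproteins APOC3 (7.64 ± 1.53) and APOA1 (6.54 ± 1.06, from 13.6 to 1329 CPM) and fibronectin, FN1 (4.92 ± 0.93). APOA1, RSPO3 (5.48 ± 0.98) and the laminin LAMA1 (4.48 ± 1.00) belong to the hypoblast list, of which 3 of 16 genes rose (9 adjusted over the list alone, adjusted p = 1.71e-09, and adjusted p = 0.0554 with an estimated correlation). Abundant hypoblast genes stood in TE_E7 at a median of 12.1% of their level in Hypoblast_E7 of the same libraries, and in Epiblast_E7 at 22.4%. KLF4 fell by 4.2 ± 1.05, the death promoter BAD by 4.2 ± 0.74 and the stress gene GADD45B by 6.82 ± 1.56. No gene of oxidative phosphorylation passed and the list leaned down (6 of 18 adjusted over the list alone, adjusted p = 2.15e-08, and adjusted p = 0.598 with an estimated correlation). Without P14, P15, P8 or P9 the count was 27, 30, 2163 or 6, and with DESeq2 size factors 79.4% of called genes were higher, against 49.4%. More were higher than lower also by DESeq2 (1161 and 452), without trended dispersion (217 and 148), with at least 6000 genes per cell (12 and 3) and without P9 (5 and 1).

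From TE_E7 to TE_E8, 7 genes passed, 4 higher and 3 lower (2 sums against 2, 20 cells against 14). KDSR, an enzyme of sphingolipid synthesis, rose by 3.87 ± 0.74, LTA4H, which makes leukotriene B, by 3.25 ± 0.67, and the mitochondrial ribosomal gene MRPL57 by 2.31 ± 0.42. TET1 fell by 3.00 ± 0.56. None of the 26 lists passed. Without P8 or P9 the count was 1056 or 2, and without P3 or P4 edgeR called 0 (1421 and 1322 at an unadjusted p under 0.05). With DESeq2 size factors 33.3% of 6 called genes were higher, against 57.1%, and DESeq2 called 167 higher and 433 lower.

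From TE_E8 to TE_E10, 30 genes passed, 25 higher and 5 lower (2 sums against 2, 16 cells against 20). The steroid enzymes CYP17A1 and CYP19A1, the aromatase, stood at 458 ± 257 and 217 ± 196 CPM (SD, n = 2) in TE_E10 and at 0 in both TE_E8 sums (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.043 and adjusted p = 0.033). Pooled with the 3 TE_E8 cells of P5, too few for a sum, TE_E8 had 1.23 CPM of CYP17A1 and 0.205 of CYP19A1. GCLC, an enzyme of glutathione synthesis, rose by 4.80 ± 0.86, the peptide transporter SLC15A2 by 6.25 ± 1.34 and UCP2, an uncoupling protein of mitochondria, by 4.38 ± 0.92, while KLHL5 fell by 4.17 ± 0.89. Of 9 genes of trophoblast secretion and steroid synthesis, CYP17A1 and CYP19A1 rose and none fell (5 adjusted over the list alone, adjusted p = 0.0185, and adjusted p = 0.744 with an estimated correlation). IFNG had a value of 7.22 ± 2.0 and POU5F1 of -1.32 ± 0.64, and neither passed. Without P4, P5 or P6 the count was 1, 9 or 1, and without P3 edgeR called 0 (968 at an unadjusted p under 0.05). DESeq2 called 178 with all libraries.

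From ICM_E6 to Hypoblast_E7 hypoblast genes rose, and 224 genes passed, 168 higher and 56 lower (2 sums against 2, 73 cells against 32). LAMC1, a laminin chain, rose by 6.25 ± 0.67, the laminin binder NID1 by 7.94 ± 1.05, and the collagens COL4A1 and COL4A2 by 4.08 ± 0.80 and 3.73 ± 0.90, while LAMA1 stood at 158 CPM in Hypoblast_E7 and at 0.0 in ICM_E6. GATA4 (4.80 ± 0.89), FOXA2 (7.59 ± 1.79) and RSPO3 (6.39 ± 0.90) rose too, and 6 of 16 hypoblast genes rose in all (11 adjusted over the list alone, adjusted p = 3.52e-10, and adjusted p = 0.0371 with an estimated correlation). STAT3 fell by 3.67 ± 0.59, KLF4 by 4.2 ± 0.93 and CDH1, the cadherin of epithelia, by 2.12 ± 0.49. CDH1 was the gene of 13 in the core pluripotency list that fell (3 adjusted over the list alone, adjusted p = 0.000151, and adjusted p = 0.0945 with an estimated correlation). Without P15 or P8 the count was 80 or 88.

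From Hypoblast_E7 to Hypoblast_E8, 55 genes passed, 33 higher and 22 lower (3 sums against 2, 129 cells against 73). The small heat shock proteins HSPB8 and HSPB1 rose by 7.71 ± 1.5 and 3.76 ± 0.78, their cochaperone BAG3 by 3.68 ± 0.80, the extracellular chaperone CLU by 6.94 ± 1.28 and the malic enzyme ME1 by 4.73 ± 0.77. OTX2 fell by 2.43 ± 0.56, IL6ST by 1.97 ± 0.43 and SYCP1, a protein of the synaptonemal complex, changed by -6.63 ± 1.21. No p53 and stress gene passed over all genes, and 6 of 10 rose when adjusted over the list alone (adjusted p = 0.000922). Core pluripotency genes leaned down (0 of 13, 5 adjusted over the list alone, adjusted p = 0.00645), and both lists had adjusted p = 0.474 with an estimated correlation. Without P4, P5, P8 or P9 the count was 8, 4, 14 or 5, and more were lower than higher without P8 (10 and 4) and P9 (5 and 0).

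Lineages were compared within libraries. How the authors assigned cells of a library to lineages is not given in the sources used here, and if the same expression values were used, the p-values of lineage comparisons are too small. Between hypoblast and epiblast, with the library as a block, 3187 of 17022 genes passed, 1750 higher and 1437 lower in hypoblast (6 libraries of E7 to E10, 270 cells against 106). More were lower than higher with DESeq2 size factors (1628 and 1470), by DESeq2 (2423 and 2022), without the block (1193 and 968) and without trended dispersion (2932 and 2607), and with at least 10 cells per sum the count was 768. All 15 measured hypoblast genes were higher (15 adjusted over the list alone, adjusted p = 1.06e-17), among them SOX17 (3.72 ± 0.48), GATA4 (3.62 ± 0.37), GATA6 (3.05 ± 0.46), FOXA2 (3.59 ± 0.51), PDGFRA (3.55 ± 0.39) and APOA1 (2.06 ± 0.20, 3780 against 1007 CPM). Of 13 core pluripotency genes 11 were lower and none higher (11 adjusted over the list alone, adjusted p = 7.21e-14), with SOX2 at -4.91 ± 0.41, NANOG at -4.84 ± 0.39 and POU5F1 at -1.80 ± 0.21, each lower in 6 of 6 libraries. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment NANOG had adjusted p = 3.15e-06. Of 15 formative genes 11 were lower, such as NODAL (-3.83 ± 0.40) and DNMT3B (-1.55 ± 0.20), and ZIC2 was higher (12 and 1 adjusted over the list alone, adjusted p = 1.52e-08). Genome activation genes were lower too, 6 of 7 (6 adjusted over the list alone, adjusted p = 6.47e-05), and so were 3 of 9 fibroblast genes, VIM, THY1 and ACTA2 (3 adjusted over the list alone, adjusted p = 0.023). Under an estimated correlation the lists had adjusted p = 0.179 (hypoblast), adjusted p = 0.127 (core and formative), adjusted p = 0.135 (genome activation) and adjusted p = 0.23 (fibroblast). The naive genes split, with TFCP2L1 (3.42 ± 0.38), TBX3 (2.77 ± 0.46) and KLF5 (1.64 ± 0.19) higher in hypoblast, and KLF17 (-3.53 ± 0.43) and FGF4 (-4.98 ± 0.67) among the 5 of 13 that were lower. BMP2 and the WNT amplifier RSPO3 were higher by 3.84 ± 0.51 and 4.04 ± 0.32, and 7 of 15 BMP genes were higher and 1 lower (9 and 4 adjusted over the list alone, adjusted p = 0.0553). Outside the lists ITM2A, a membrane protein, had the lowest value, -6.08 ± 0.36.

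**Figure D2:**
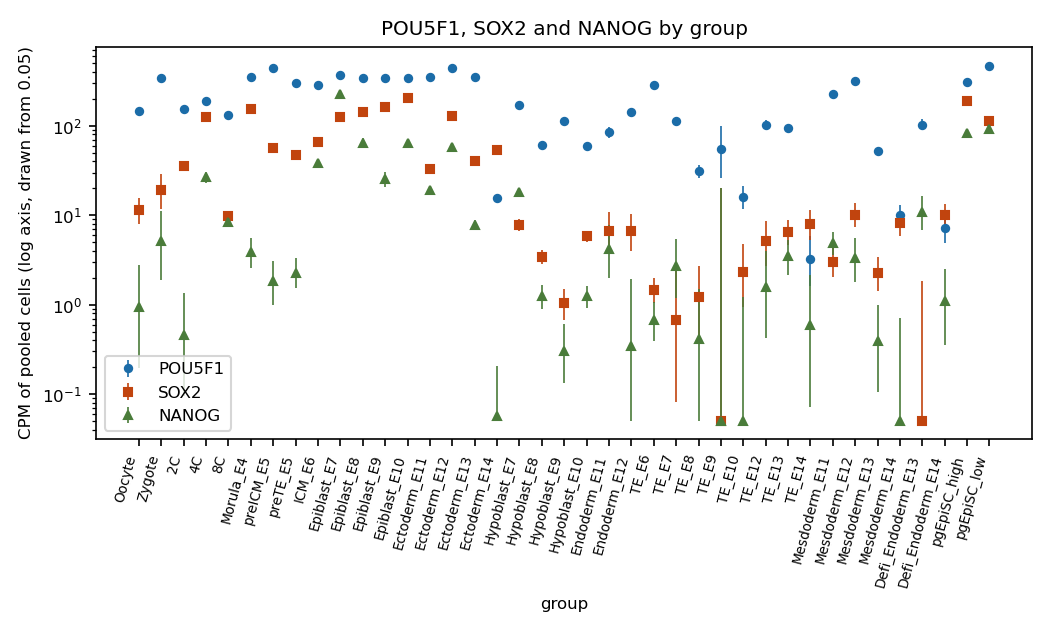
POU5F1, SOX2 and NANOG in each group, in CPM of the pooled cells on a log axis, with 95% Poisson intervals that cover counting error only. NANOG stands at 228 in Epiblast_E7 and 18.3 in Hypoblast_E7, and SOX2 at 124 and 7.76.

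Trophoblast cells shared 3 libraries with enough epiblast cells, of E7 and E8, and 1212 of 11389 genes passed there, 560 higher and 652 lower (28 cells against 42). GATA2 was higher by 4.75 ± 0.63, GATA3 by 4.39 ± 0.60, TFAP2A by 4.57 ± 0.68, and the prostaglandin synthase PTGS2 by 4.73 ± 0.63. Of 12 trophoblast genes 9 were higher and none lower (10 adjusted over the list alone, adjusted p = 2.84e-10), and of 6 genes of trophoblast secretion 3, with the steroid enzyme CYP11A1 (3.37 ± 0.63) among them (3 adjusted over the list alone, adjusted p = 0.000474). ATP6V0A4, a subunit of the proton pump, was higher by 5.95 ± 0.76. Of 13 core pluripotency genes 8 were lower (9 adjusted over the list alone, adjusted p = 1.5e-07), with SOX2 at -7.81 ± 0.92, NANOG at -6.24 ± 0.73 and POU5F1 at -2.43 ± 0.59. DNMT3B was 1 of 3 lower genes among 9 formative ones (-3.44 ± 0.57; 6 adjusted over the list alone, adjusted p = 0.000474). With an estimated correlation the trophoblast, secretion and core lists had adjusted p = 0.465 and the formative list had adjusted p = 0.622. Without P4 or P8 the count was 718 or 302, with 384 higher and 334 lower without P4, and without the block it was 775.

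Against hypoblast, trophoblast cells of 6 libraries of E7, E8 and E10 differed in 2444 of 13788 genes, 1030 higher and 1414 lower (50 cells against 218). GATA2 was higher by 4.39 ± 0.35, GATA3 by 4.09 ± 0.30, CDX2, a factor of trophectoderm and gut, by 3.39 ± 0.60, KRT7 by 2.87 ± 0.40 and KRT18 by 2.76 ± 0.23. Of 13 trophoblast genes 9 were higher and TEAD4 lower (-1.40 ± 0.27; 9 and 1 adjusted over the list alone, adjusted p = 1.61e-11, and adjusted p = 0.0165 with an estimated correlation). Secretion genes followed, 5 of 8 higher (7 adjusted over the list alone, adjusted p = 1.5e-06), as PTGS2 (5.24 ± 0.38), CYP11A1 (4.18 ± 0.39), HSD17B1 (3.44 ± 0.46), IFNG (3.80 ± 0.97), an interferon that pig trophoblast releases, and the steroid enzyme CYP17A1 (3.20 ± 0.91), which was higher in 2 of 6 libraries. All 15 measured hypoblast genes were lower (15 adjusted over the list alone, adjusted p = 4.53e-14), with PDGFRA at -4.02 ± 0.41, HNF4A at -3.58 ± 0.33 and GATA4 at -2.90 ± 0.27. BMP genes were lower as well, 9 of 14 (9 adjusted over the list alone, adjusted p = 0.00132), BMP2 by most (-4.14 ± 0.47). Under an estimated correlation the secretion list had adjusted p = 0.141, the hypoblast list adjusted p = 0.134 and the BMP list adjusted p = 0.2. POU5F1 differed by -0.95 ± 0.26. Without the block 1043 genes were higher and 961 lower.

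Mesoderm against ectoderm, a comparison added after the data were seen, called 491 of 15832 genes, 295 higher and 196 lower in mesoderm (6 libraries of E11 to E14, 95 cells against 218). The matrix proteoglycans LUM and DCN were higher by 5.11 ± 0.35 and 4.40 ± 1.06, each in 4 of 6 libraries, and the collagens COL1A1, COL1A2 and COL3A1 by 2.57 ± 0.51, 2.81 ± 0.55 and 3.6 ± 0.74. These values mix days: at E11 to E12 DCN, COL1A1, COL1A2 and COL3A1 had -3.07, -0.04, -2.28 and -1.86, and at E13 to E14 they had 5.36, 3.40, 3.29 and 4.00, a change that passed for all but COL3A1. The early values are given without a test or error, and COL3A1 stood at 0.0 CPM in pooled Mesdoderm_E12 cells. A negative early value therefore does not by itself show higher expression in ectoderm. The 5 genes belong to the fibroblast list, of which 6 of 10 genes were higher (9 up and 1 down adjusted over the list alone, adjusted p = 1.14e-05, and adjusted p = 0.329 with an estimated correlation). HAND1 was higher by 2.40 ± 0.29, BMP4 by 2.13 ± 0.22, PDGFRA by 1.91 ± 0.25 and SNAI2, a factor of cell migration, by 2.91 ± 0.60. PDGFRA was 1 of 5 higher genes of 16 in the hypoblast list (9 adjusted over the list alone, adjusted p = 2.97e-07), and HAND1 was 1 of 3 of 12 in the trophoblast list (5 adjusted over the list alone, adjusted p = 0.00011). SOX2 was lower by 3.41 ± 0.40 on the log2 scale, NANOG by 3.46 ± 0.72, POU5F1 by 1.66 ± 0.33 and CDH1 by 1.88 ± 0.32, and 5 of 13 core pluripotency genes were lower (9 adjusted over the list alone, adjusted p = 2.97e-07). Of 16 formative genes 7 were lower, including OTX2 (-2.46 ± 0.43) and SFRP2 (-3.86 ± 0.50) (12 down and 1 up adjusted over the list alone, adjusted p = 1.07e-08). TBXT, the mesoderm factor brachyury, had a value of -1.20 ± 1.83, with 0.52 in P6 (E11), 2.51 in P10 (E12), -3.30 and -3.86 in P18 and P19 (E13) and -0.74 and 0.0 in P12 and P13 (E14). Of the 12 genes of primitive streak and mesoderm 2 were higher and 1 lower (2 and 1 adjusted over the list alone, adjusted p = 0.448). With an estimated correlation the core list had adjusted p = 0.175, the formative and trophoblast lists adjusted p = 0.0846 and the hypoblast list adjusted p = 0.16. Without P12, P13, P18 or P19 the count was 121, 324, 102 or 221, and without the block it was 40.

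Both pgEpiSC samples were compared with Epiblast_E10, the day their labels name: 1092 of 16737 genes passed, 552 higher and 540 lower in pgEpiSC (2 sums against 2, 189 cells against 97). The spread between the pgEpiSC sums includes any difference between low and high. Of the pluripotency factors, POU5F1 stood at 408 CPM in pgEpiSC and 303 in the epiblast (0.43 ± 0.22), NANOG stood at 91.4 and 58.1 (0.65 ± 0.27) and SOX2 stood at 155 and 177 (-0.20 ± 0.29), with none past edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.336, adjusted p = 0.201 and adjusted p = 0.795). Among the genes that fell were some known from germ cells, a theme picked out after the values of GTSF1 and TDRKH were seen. GTSF1, a partner of piRNA proteins (ENSSSCG00000026333), fell by 8.53 ± 0.33, from 184 to 0.46 CPM. TDRKH, which carries piRNA precursors (ENSSSCG00000027770), fell by 5.21 ± 0.37, HENMT1, which methylates piRNA, by 3.89 ± 0.46, and the germ cell helicase DDX4 by 3.68 ± 0.57. DPPA2, DPPA4 and DPPA5, genes of early embryos and pluripotent cells, fell by 4.95 ± 0.40, 5.93 ± 0.49 and 5.47 ± 0.61. With GDF3 (-1.76 ± 0.36) and TDGF1 (-2.41 ± 0.37), DPPA2 and DPPA4 were the 4 of 13 core pluripotency genes that fell (5 adjusted over the list alone, adjusted p = 0.00896). Of 7 primordial germ cell genes 4 fell, and KIT (2.19 ± 0.36) and TFAP2C (2.51 ± 0.58) rose (5 and 2 adjusted over the list alone, adjusted p = 0.047). Naive genes fell in 4 of 13 cases and rose in 2 (6 and 2 adjusted over the list alone, adjusted p = 0.0138). Trophoblast genes fell in 5 of 13 cases (7 down and 1 up adjusted over the list alone, adjusted p = 0.000651), GATA2 from 3.30 to 0.0655 CPM and TFAP2A from 2.25 to 0.05 CPM. With an estimated correlation the core, naive and trophoblast lists had adjusted p = 0.353 and the germ cell list had adjusted p = 0.356.

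LEFTY2, a feedback inhibitor of NODAL (ENSSSCG00000032299), rose by 7.77 ± 0.63, from 2.06 to 459 CPM, CER1 by 6.90 ± 1.08 and SMAD3 by 4.78 ± 1.11, and 4 of 13 genes of TGF-beta and Nodal signalling rose while 2 fell (4 and 2 adjusted over the list alone, adjusted p = 0.233). FOXA2 rose by 6.43 ± 1.27 and the primed factor ZIC2 by 2.14 ± 0.38. Energy genes rose by small amounts: 10 of 18 genes of oxidative phosphorylation (12 adjusted over the list alone, adjusted p = 7.01e-08), such as NDUFA4 (1.01 ± 0.15) and COX7A2 (1.06 ± 0.16), and 7 of 17 of glycolysis (11 adjusted over the list alone, adjusted p = 4.02e-06), such as ENO1 (1.52 ± 0.21), PGAM1 (1.17 ± 0.19) and GAPDH (0.70 ± 0.13). No gene of the maternal uterus, blood and cumulus list passed (4 of 7 lower adjusted over the list alone, adjusted p = 0.00896). The maternal and oxidative phosphorylation lists had adjusted p = 0.353 with an estimated correlation, and the glycolysis list had adjusted p = 0.356. Also higher were ATP1B1, a sodium pump subunit (3.37 ± 0.23), and the neurokinin TAC3 (3.39 ± 0.55), and lower was the matrix protein MGP (-8.37 ± 0.55). Against Ectoderm_E11 the values of COX7A2, ENO1, PGAM1 and GAPDH were -0.02, -0.17, -0.09 and -0.01, and that of SOX2 was 1.96. Against Epiblast_E8 that of TFAP2C was -2.26. Without P15, P16, pgEpiSC_high or pgEpiSC_low the count was 284, 552, 707 or 263. More were lower than higher without P15 (173 and 111), without pgEpiSC_low (148 and 115), by DESeq2 (977 and 898), with its size factors (544 and 540), with no filter (1013 and 811), with at least 10 cells per sum (760 and 740), against Ectoderm_E11 (554 and 297) and against Epiblast_E8 (1140 and 1008).

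**Figure D3:**
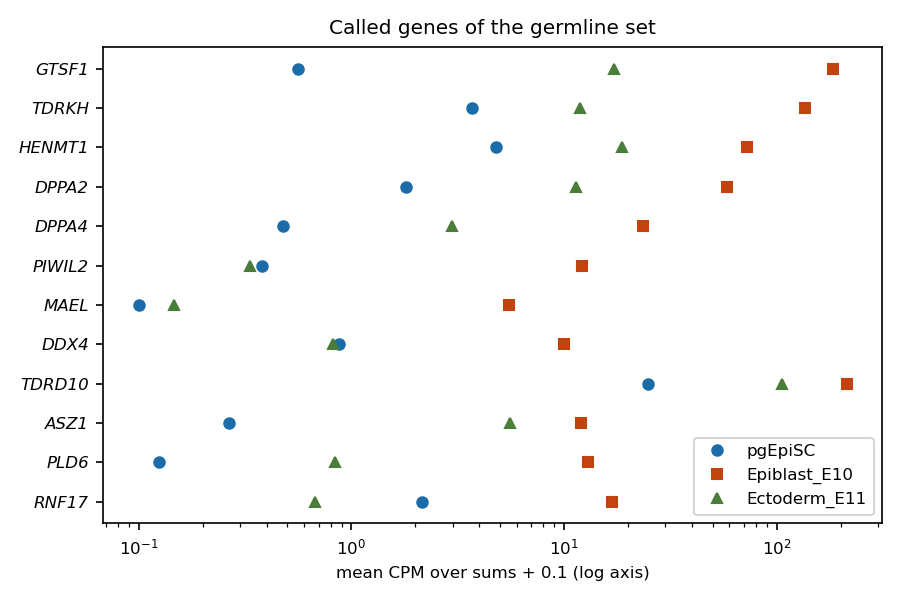
Mean CPM over sums, on a log axis with 0.1 added, of 12 genes known from germ cells or the piRNA pathway that were lower in pgEpiSC than in Epiblast_E10, with Ectoderm_E11 beside them. The set was chosen after values of GTSF1 and TDRKH were seen, and GTSF1 stands at 0.46, 184 and 17.1 CPM in pgEpiSC, Epiblast_E10 and Ectoderm_E11. Both are among the 12, as are DPPA2 and DPPA4, which also belong to the core pluripotency list.

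Between pgEpiSC_high and pgEpiSC_low no test was possible, with 1 library each, and the intervals given are 95% Poisson intervals that cover counting error only. Of 4456 genes at 50 CPM or more, 24 were at least 2-fold higher and 36 at least 2-fold lower in pgEpiSC_high (1.35%). BNIP3, which marks low oxygen and mitochondrial turnover, had 40.1 CPM in high and 306 in low, a log2 ratio of -2.90 (-3.04 to -2.82). With it, LDHA (-1.75), PDK1, which diverts pyruvate from mitochondria (-1.54), and the glucose transporter SLC2A3 (-1.48) were lower in high. The glycolysis list of 17 genes, 2 of them at least 2-fold lower, lay at percentile 0.0 of 10000 random lists matched on expression. The lists of TGF-beta and Nodal signalling (13 genes, 5 at least 2-fold lower), definitive endoderm (4 genes, 3), FGF signalling (14 genes, 2) and formative pluripotency (13 genes, none lower and SFRP2 higher) lay at percentile 0.0 as well. Those of WNT signalling (0.2), DNA methylation (0.3), primitive streak (1.5) and BMP signalling (1.7) were also low, and the highest was primordial germ cell (97.1). Random lists draw genes singly and some lists share genes, so these percentiles are not p-values and low ones are not particular to single lists. LEFTY2 (-1.27), CER1 (-1.66) and FOXA2 (-1.83), which rose in pgEpiSC against the epiblast, were lower in high than in low. TAC3 had a ratio of 1.84 (1.75 to 1.97), the apolipoprotein APOA1 of 1.68 and SFRP2 of 1.52. POU5F1 had -0.62, SOX2 0.74 and NANOG -0.17. With TMM factors 14 of 4452 genes were higher and 61 lower. With a minimum of 10 CPM in place of 50, 373 genes differed by at least 2-fold.

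Across the 2000 genes that varied most between embryonic groups, both pgEpiSC samples were closest to Epiblast_E10. The Spearman correlation across genes, which are not replicates, was 0.862 for pgEpiSC_high and 0.845 for pgEpiSC_low with the pooled cells of that group. With its libraries taken apart it was 0.853 to 0.855 and 0.838 to 0.839. Ectoderm_E12 came next, at 0.824 and 0.807, and the lowest value was that of 8C, -0.112 and -0.095. Epiblast_E10 stayed the closest group under all 6 alternatives, in some by little. With the deposited means it had 0.921 in pgEpiSC_low and 0.93 in pgEpiSC_high, against 0.919 and 0.923 for Ectoderm_E12. With all genes of at least 5 CPM it had 0.936 and 0.943, against 0.932 and 0.939 for Ectoderm_E13.

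**Figure D4:**
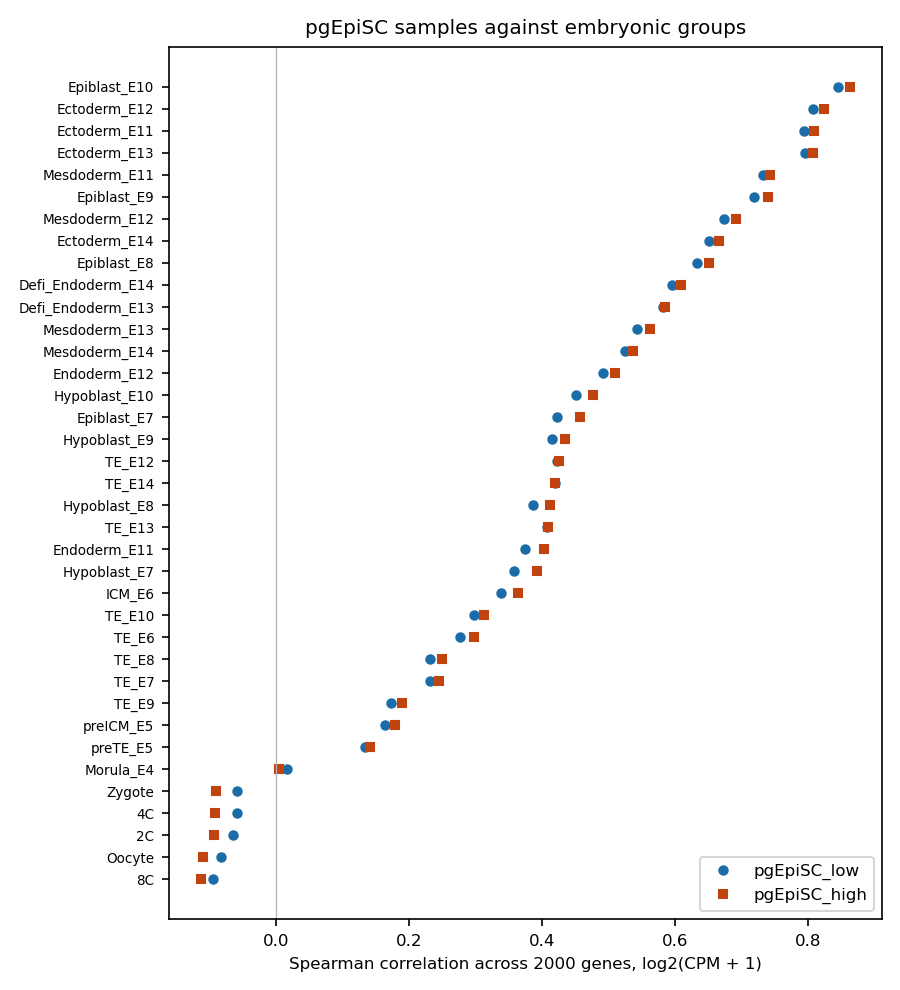
Spearman correlation across 2000 genes of pgEpiSC_low (circles) and pgEpiSC_high (squares) with the pooled cells of each embryonic group. Epiblast_E10 has the highest value for both, 0.845 and 0.862.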

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

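Chosen only after the results were seen were the tests of RNA exchanged between the cells of a library and of libraries shared by both kinds of cells, the comparison of mesoderm with ectoderm, the set of germline genes and the tests of differences between embryonic days. The thinned sums and the comparison with Ectoderm_E11 were chosen after the data were seen but before their own results were, and so were the other tests of the first 3 patterns and the splits that exchange groups within libraries.

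The 8C cells lay closer to the 2C profile than to the 4C or Morula_E4 profile, and the 4C sums of P1 and P13 stood apart. The genes lower in 8C than in 4C and higher in Morula_E4 had a median log2 difference of -0.01 (-0.02 to 0.01, 1323 genes) between the Ectoderm_E13 sums of P19, which also holds 8C cells, and P18, which argues against a shift of the whole library P19. In the 4C sum of P1, 8.3% of 4833 genes (400 genes) lay at least 2-fold above both the 2C and the Morula_E4 sum of P1. The same share was 3.6% for the Zygote sum of P1. The 4C sum is thus more than a mix of 2C and Morula_E4 RNA. Whether Morula_E4 RNA entered these cells cannot be told from this, since 4C cells also have RNA of their own. For 23 genes high in Morula_E4 and near 0 in 8C, 4C stood at 47.2% of Morula_E4 of P1 in P1 and at 4.5% in P13. That source stays open. Of 80 8C cells 0.0% (0 cells, upper limit 4.5%) were closest to the pooled 4C or Morula_E4 cells, which restates the pattern and, contrary to the bound set for it, cannot exclude cells of earlier stages, since a group made up of these would give the same value. A wrong label and a difference in developmental timing between embryos stay open, and neither was tested, since the labels name no embryos.

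Hypoblast list genes were higher in TE_E7 than in TE_E6. Of 43 abundant hypoblast genes, 2.3% (0.1 to 12.3) lay more than 3-fold below the share of their Hypoblast_E7 level that the called list genes had in TE_E7, so that RNA or cells of the hypoblast remain a candidate source. APOA1, the most abundant list gene, stood at 1053 CPM in TE_E7, 26.7% of Hypoblast_E7, and at 13 in TE_E6. In Epiblast_E7 the same 43 genes stood at 185.8% (130.9 to 313.4) of their share in TE_E7. They were picked for at least 100 CPM in Hypoblast_E7 and at most 5% of that in TE_E6. Genes that the epiblast itself expresses can be among them, so this value cannot decide whether RNA was exchanged within a library. It took 12 of the 14 TE_E7 cells to reach 90 percent of the summed level of the list, which argues against a few misplaced cells. Expression by the trophectoderm itself was not tested.

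Of 27 genes of germ cells and the piRNA pathway, chosen after GTSF1 and TDRKH were seen, 17 were tested and 12 were lower in pgEpiSC than in Epiblast_E10 and none higher, whereas of the fixed primordial germ cell list 4 were lower and 2 higher (KIT and TFAP2C). GTSF1 and TDRKH, which prompted the choice, are themselves among the 12. So are DPPA2 and DPPA4, which also belong to the core pluripotency list. The count of 12 is therefore no independent support for a germline theme. The 12 had a median of -5.34, and of -5.34 too with the 1 gene without counts in pgEpiSC set at its bound from 3 counts over both sums. When the pgEpiSC and Epiblast_E10 sums were thinned to about 13468167 counts each, 100.0% of the 12 stayed past the threshold, which argues against depth. The sums of the other epiblast days in the fit were smaller and were not thinned. As 0 libraries hold both kinds of cells, a difference between library batches cannot be told apart from the difference between pgEpiSC and embryo. Against Ectoderm_E11 the median was -2.29 (-3.96 to -1.14), from -5.08 for GTSF1 to 1.65 for RNF17. Of the 12, 8 stayed lower past the threshold. The interval reaches past the bound set for this test, and the 12 were picked for low values in the same pgEpiSC sums. Whether a match to that day is the cause therefore cannot be told. Later days and a loss during derivation or culture were not tested.

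Exchanging the groups within libraries gave other splits of the same sums. For hypoblast against epiblast 1 of 32 splits, the real one, gave as many as 3187 genes and the highest other gave 6, and for trophoblast against hypoblast it was again 1 of 32, with 2444 genes and 7. For mesoderm against ectoderm 1 of 32 gave as many as 491 and the highest other gave 46, but if lineages were drawn from the same expression values the real split is favoured, so these splits do not exclude chance. For trophoblast against epiblast the 4 splits are too few for a share under 0.05, with 1212 genes in the real split and 0 in the highest other.

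Differences between lineages were tested for change with embryonic day by an interaction term in edgeR, later days minus earlier. The differences within the earlier or the later days alone are given without a test or error. Their sign is uncertain for genes with very few counts. For hypoblast against epiblast 306 genes differed between E7 and the days E8 to E10, 200 upward and 106 downward. TEAD4 changed by -1.50, from a lineage difference of 1.92 to 0.42, and ETV5 by -3.69, from 0.92 to -2.77. For trophoblast against hypoblast 4 genes differed between E7 to E8 and E10, 3 upward and 1 downward, and the steroid enzyme CYP17A1 changed by 6.91, from -1.84 to 5.07.

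For mesoderm against ectoderm 239 genes differed between E11 to E12 and E13 to E14, 133 upward and 106 downward. Among them DCN changed by 8.43, from a lineage difference of -3.07 to 5.36, COL1A2 by 5.57, from -2.28 to 3.29, COL1A1 by 3.44, from -0.04 to 3.40, TAGLN by 2.68, LAMA1 by 1.69 and COL4A1 by 1.59, while COL3A1 (5.87) did not pass. IFNGR1 changed by 4.26, IFNAR2 by 2.69 and CCN4 by 3.82. Downward went ACSL4 (-2.68), UPP1 (-2.39) and NSG1 (-2.14).

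In 8 of 79 groups of 6 libraries (1 gene in 1 comparison each) a single library stood far from the others, where chance gives about 1 in 20 groups. In hypoblast against epiblast GJB1 was 6.41 in P16 (others 2.89 to 3.68), ITM2A was -4.50 in P16 (others -6.48 to -5.99) and NANOG was -2.73 in P9 (others -5.81 to -4.81). Trophoblast against hypoblast had all its cases in P3: CLDN1 at -8.97 (others -4.60 to -2.68), NOSTRIN at -8.35 (others -4.75 to -3.21) and DHRS3 at -6.55 (others -3.94 to -3.29). Mesoderm against ectoderm had MAB21L2 at 5.41 in P19 (others 1.93 to 3.09) and SOX2 at -1.17 in P13 (others -4.46 to -3.53).

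Spike-in RNA was used in no comparison. In P1 the median number of pig counts per spike-in count was 263 in Oocyte (quartiles 27.6 and 643 over 4 cells), 81.1 in Zygote, 331 in 2C, 162 in 4C and 87.4 in Morula_E4. In P13 it was 156 in 2C and 43.1 in 4C, so it differed between libraries for the same group.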

How the results depend on the processing

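The minimum of 6000 genes per cell, the fit without trended dispersion, the thinned sums, the 2C and 4C sums alone and the comparison with Ectoderm_E11 were tests chosen after seeing the data, as was mesoderm against ectoderm; all others were planned. Stage steps are named by their later group, and counts are of genes past the threshold unless stated. The cause was not tested, except where fewer libraries, cells or genes tested give it.

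With each library left out in turn the counts ranged from 0 to 1506 for 4C, 795 to 3325 for 8C, 4150 to 5795 for Morula_E4, 84 to 200 for Epiblast_E7, 3 to 63 for Epiblast_E8, 2 to 24 for Ectoderm_E11, 11 to 41 for Ectoderm_E14, 0 to 18 for preTE_E5, 204 to 1020 for TE_E6, 6 to 2163 for TE_E7, 0 to 1056 for TE_E8, 0 to 9 for TE_E10, 80 to 160 for Hypoblast_E7, 4 to 77 for Hypoblast_E8 and 0 to 7 for Mesdoderm_E14. At the counts of 0 edgeR gave 452 (4C), 913 and 1067 (preTE_E5), 1421 and 1322 (TE_E8), 968 (TE_E10) and 1174 (Mesdoderm_E14) genes at an unadjusted p under 0.05, and no other tool was run on those sets. Ranges were 2310 to 3064 for hypoblast against epiblast, 302 to 943 for trophoblast against epiblast, 1816 to 2854 for trophoblast against hypoblast, 102 to 688 for mesoderm against ectoderm and 263 to 707 for pgEpiSC. Where a group kept 1 sum, it was assumed to vary like the others.

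Without trended dispersion the counts were 2156 (4C), 6864 (8C), 1084 (Epiblast_E7), 612 (Epiblast_E8), 1758 (Ectoderm_E11), 1889 (Ectoderm_E14), 151 (preTE_E5), 3243 (TE_E6), 365 (TE_E7), 28 (TE_E8), 56 (TE_E10), 900 (Hypoblast_E7), 1123 (Hypoblast_E8), 146 (Mesdoderm_E14), 5539 (hypoblast against epiblast), 1660 (mesoderm against ectoderm) and 4153 (pgEpiSC). The DESeq2 Wald test gave 3932 (8C), 1311 (Epiblast_E7), 884 (Epiblast_E8), 365 (Ectoderm_E11), 255 (Ectoderm_E14), 146 (preTE_E5), 2462 (TE_E6), 1613 (TE_E7), 600 (TE_E8), 178 (TE_E10), 835 (Hypoblast_E7), 344 (Hypoblast_E8), 179 (Mesdoderm_E14), 1340 (mesoderm against ectoderm) and 1875 (pgEpiSC). With no filter on low counts there were 865 (Epiblast_E7), 654 (Epiblast_E8), 249 (Ectoderm_E11), 323 (Ectoderm_E14), 147 (preTE_E5), 1757 (TE_E6), 697 (TE_E7), 187 (TE_E8), 165 (TE_E10), 668 (Hypoblast_E7), 419 (Hypoblast_E8), 113 (Mesdoderm_E14), 1396 (mesoderm against ectoderm) and 1824 (pgEpiSC).

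At least 10 cells per sum gave 833 (Epiblast_E7), 81 (Ectoderm_E11), 130 (Ectoderm_E14), 523 (Hypoblast_E7), 122 (Hypoblast_E8), 5 (Mesdoderm_E14), 768 (hypoblast against epiblast), 121 (mesoderm against ectoderm) and, for preTE_E5, 0 by edgeR (1365 at an unadjusted p under 0.05; no other tool was run). At least 6000 genes per cell gave 254 (Epiblast_E8), 62 (Ectoderm_E11), 35 (preTE_E5), 15 (TE_E7), 1 (TE_E8), 344 (Hypoblast_E7) and 3 (Mesdoderm_E14). DESeq2 size factors gave 2 (preTE_E5), 393 (TE_E7) and 3 (Mesdoderm_E14). The 2C and 4C sums alone gave 21 for 4C with the library as a block and 0 without (774 at an unadjusted p under 0.05; no other tool was run), and of 24 gene values 21 and 22 fell short of the threshold. No block gave 775 for trophoblast against epiblast and 40 for mesoderm against ectoderm, and Epiblast_E8 in place of Epiblast_E10 gave 2148 for pgEpiSC. With mitochondrial genes left out, all 20 counts stayed within 1.5 times.

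Lists past the threshold of camera with an estimated correlation numbered 3 (Ectoderm_E11), 2 (Ectoderm_E14), 1 (Hypoblast_E7), 1 (trophoblast against hypoblast) and 0 in the others where camera with its preset correlation had called any. By fry they numbered 9 (Morula_E4), 1 (Epiblast_E7), 1 (Hypoblast_E7), 10 (hypoblast against epiblast), 14 (trophoblast against hypoblast) and 0 (Epiblast_E8, preTE_E5, TE_E10, Hypoblast_E8, Mesdoderm_E14 and trophoblast against epiblast), and the other 9 comparisons stayed within 1.5 times.

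Without a test, a minimum of 10 CPM gave 373 genes at least 2-fold apart between high and low. Mean CPM gave 1312 for Zygote and 458 for Hypoblast_E10, and the deposited means gave 688 for Zygote and 261 for Ectoderm_E13. Similarity to Epiblast_E10 was 0.936 for pgEpiSC_low and 0.943 for pgEpiSC_high with all genes of at least 5 CPM, 0.824 and 0.851 with 500 genes, 0.858 and 0.872 with Pearson's correlation, 0.841 and 0.859 with mean CPM, 0.921 and 0.93 with the deposited means, and 0.744 and 0.795 with 10 cells per group.

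Of single genes, the pgEpiSC values against Ectoderm_E11 reversed for FOLR1 (0.35), SOX2 (1.96), COX7A2 (-0.02), ENO1 (-0.17), GAPDH (-0.01) and PGAM1 (-0.09), and against Epiblast_E8 for TFAP2C (-2.26). Without P1 reversed NANOG (-0.75, and 7.19 without P13), DPPA2 (-0.84 and 4.50), SMAD7 (-1.08 and 4.84) and ZFP42 (-1.33 and 5.42) in 4C, and KLF4 in 8C (0.24 and -4.15). Of 2679 gene values with a library left out, 1890 kept direction and side of the threshold, 784 fell short of it and 5 reversed. Few values of genes named for size could reverse, since these were chosen for the same direction in every sum. With DESeq2 583 of 603 were the same, with its size factors 595 of 619, without a filter 607, without mitochondrial genes 611, without trended dispersion 599, with 10 cells per sum 413 of 447 and with 6000 genes per cell 580 of 617. Log2 ratios without a test were less stable. With mean CPM over cells 31 of 530 moved by at least 2-fold. With the deposited means, which are on another log scale, 327 of 485 did so and 158 stayed, and none reversed under either setting.

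Not run were the minimum of 2000 genes per cell, which removes 0 cells, other clusterings, since the authors' grouping was used, and the settings planned for pgEpiSC without a test. At least 10 cells per sum left too few sums for both trophoblast comparisons and for Epiblast_E8, TE_E7, TE_E8 and TE_E10. Thinning the pgEpiSC and Epiblast_E10 sums to equal totals left the pgEpiSC count within 1.5 times, and what depth limits elsewhere was not tested.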

Other observations

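Chosen after the data were seen were the genes followed through the sums of P1 and the Y-linked genes. The steps below were set beforehand and were not tested, because a group had too few libraries. Each compares pooled cells and names genes by the size of their log2 ratio, with a pseudocount of 1 CPM.

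From TE_E12 to TE_E13 CYP17A1 and CYP19A1 had ratios of -3.38 and -3.58. In TE_E14 the serum protein genes AFP and FGG had ratios of 8.39 and 5.98 against TE_E13, A2M stood at 78.2 CPM with 0.0 in TE_E13, and POU5F1 had -4.51.

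In the inner cells PDGFRA went from 16.9 CPM in Morula_E4 to 213 in preICM_E5 (3.58), while the oocyte genes BMP15 and ZP3 had ratios of -5.67 and -5.54. NANOG went from 1.84 CPM in preICM_E5 to 38.3 in ICM_E6 (3.79), with APOE (4.44) and APOC3 (5.32). From Epiblast_E8 to Epiblast_E9 the stress genes TRIB3 (-5.60), HSPB8 (-5.20) and ATF3 (-4.79) were lower, and in Epiblast_E10 ID3 (4.02) and OTX2 (2.40) were higher than in Epiblast_E9. SOX2 had 32.9 CPM in Ectoderm_E11 and 128 in Ectoderm_E12 (1.92). Hypoblast_E9 had higher DKK1 (4.26), an inhibitor of WNT, and IHH (2.96), and lower CHAC1 (-6.29) and NUPR1 (-6.10), genes of the stress response, than Hypoblast_E8.

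At gastrulation and after it, Mesdoderm_E13 had 848 CPM of CXCL14 and 243 of LUM, both at 0.0 in Mesdoderm_E12, with COL3A1 at 123 CPM against 0.0 and a ratio of 7.29 for DCN, while NODAL (-4.30) and POU5F1 (-2.55) were lower. Defi_Endoderm_E13 had a ratio of 5.50 for LEFTY2 and 3.14 for NANOG against Endoderm_E12. In Defi_Endoderm_E14 AFP stood at 706 CPM, HOXA9 at 130.2 and HOXA5 at 98.9, each with 0.0 in Defi_Endoderm_E13. Between Oocyte (4 cells) and Zygote (6 cells) 2126 of 6563 genes differed by at least 2-fold, 1752 of them downward. The count was 1312 by mean CPM over cells and 688 by the deposited means. Of the 4 Oocyte cells 1 lay closest to the pooled Oocyte profile, 2 to Zygote and 1 to 2C. Between Zygote and 2C 1728 of 5371 genes differed, with 1241 upward.

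Library P1 held cells from Oocyte to Morula_E4. For 161 genes high up to 8C and near 0 in the Morula_E4 sum of P2, the Morula_E4 sum of P1 stood at a median of 6.9% of the 2C sum of P1. The 0.71% of the Morula_E4 sum of P2 was fixed by that choice of genes, so no conclusion is drawn from the contrast. GDF9, a growth factor of oocytes, stood at 223 CPM in Morula_E4 of P1 and at 9.92 in that of P2. For 23 genes high in Morula_E4 and near 0 in 8C, the sums of P1 stood at 15.8% (Zygote), 5.1% (Oocyte), 3.3% (2C) and 47.2% (4C) of Morula_E4 of P1, and those of P13 at 2.6% (2C) and 4.5% (4C). In both pgEpiSC samples the Y-linked EIF1AY was found, at 25.6 CPM in low and 15.9 in high, and KDM5D at 2.30 in both.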
